A study of Mus musculus with 24 samples.

How the data were processed

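Peak lists of 22 CUT&RUN libraries from 2 mouse melanoma lines were analysed, 10 from the Kmt2d WT line 971 and 12 from the Kmt2d mutant line 493. Cells were grown in DMEM/F12 with fetal bovine serum and profiled with an Epicypher CUT&RUN kit. Reads were aligned and peaks called upstream with Bowtie2, FastQC, MACS2 and MultiQC on mm10 per the submitters' processing notes. Versions, settings, thresholds and the control used by the caller were not given in the sources used here. Each peak carried the deposited score, the authors' fold enrichment (a ratio), and the authors' −log10 p and −log10 q. The score was the deposited −log10 q scaled and truncated to a whole number. The lowest −log10 q per list ran from 1.30 to 1.59. All 197727 peaks were distinct, and all were used on every chromosome they named.

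Genes were the 21900 protein-coding genes of the GRCm38.p6 RefSeq gene table, the assembly of mm10. A promoter was taken as 1 kb around either end of a gene because the table gives no strand, and such a peak is called a gene-end peak. Peaks farther than 5 kb from any gene end are given as a separate class. A target peak was shared if it overlapped a peak of the other list by at least 1 bp. Shares carry Wilson 95% intervals for counting error only. Overlaps of KMT2D were compared with 100 shuffles of its positions within chromosomes.

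A gene counted as WT only or mutant only if 1 list had a gene-end peak and the other had none. For named genes the rule was stricter: no peak of the same target within 5 kb of the gene in the other line. Genes were named from the 10 with the highest fold enrichment within each list, for the 6 targets with at least 1000 peaks in both lines. For KMT2D the 10 highest gene-end genes and 10 highest distal peaks were taken, the latter with the nearest gene. Where 1 peak served a pair of genes, both were named. Other genes were named as members of a list or after their values were seen, as stated there.

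The 14 gene lists, 220 genes in all, were pigment cell, mesenchymal state, glycolysis, IGF signalling, COMPASS, SWI/SNF, ribosomal protein, Hoxa and Hoxb and tumour model genes, fibroblast, keratinocyte, blood cell and endothelial markers, and silent tissue-restricted genes. All 220 were found in the gene table. Each list was set beside 10000 random gene lists matched on classes of fold enrichment in the line that had the peaks. These percentiles describe the lists and are no test.

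Retention was the share of WT peaks of a target that overlapped a mutant peak of that target. Peaks with KMT2D were compared with peaks without it, reweighted to the same mix of 10 classes of WT fold enrichment and of gene-end class. Loci were counted with 20 kb on each side. A stretch without peaks was a run of at least 20 kb between neighbouring peaks of 1 line, all its libraries pooled, and stretches were ranked by the peaks of the other line inside.

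The depth at which each library was called was reconstructed from the authors' fold enrichment and −log10 p at the summits, taking the default mouse genome size of the caller and the shortest peak as fragment length. Ratios between libraries do not depend on the genome size. The caller scales the larger of library and control down, so the depth used ran from 0.862 M to 1.20 M fragments (M for mega) in WT lists and from 0.405 M to 2.21 M in mutant lists, while the libraries themselves ran up to 2.62 M and 5.54 M. The mutant to WT ratio of caller depth was 0.394 for SMARCC1 and otherwise ran from 1.58 (UTX) to 2.37 (ARID2). For an equal-depth comparison, called thinning here, the summit fragments and the background of the deeper list were scaled down by the depth ratio. Peaks whose −log10 p then fell under the lowest of the other list were dropped, and peaks whose fragments could not be recovered were kept.

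Retention, overlap and depth steps were checked on simulated data. Over 200 draws with a simulated retention difference of 0, 10 and −10 points, the matched estimate averaged 0.144, 9.95 and −10.0, and its interval held the true value in 94.0%, 92.5% and 95.5% of draws. The simulated peaks had no gene-end class, and peaks without KMT2D were common at every strength. Some classes of the UTX comparison held no peak without KMT2D, so this coverage need not hold for the UTX interval. All 2000 simulated overlaps were recovered. The check of thinning applied the thinning rule itself, so it did not compare thinning with peaks called anew at lower depth.

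The comparisons, gene lists and main settings were fixed before the data were examined. The equal-depth comparison, the matching on UTX, the removal of regions called in at least 15 libraries, the locus counts, the stretches without peaks and the use of 4 list counts as main results were added later. A motif analysis was not run, because it needs a genome sequence, which was not used here. Random draws used seed 7. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.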

Results

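The series mapped chromatin proteins and the promoter mark H3K4me3 by CUT&RUN, in which an antibody tethers a nuclease that releases the bound DNA, in 2 mouse melanoma cell lines. Line 971 was wild type for Kmt2d (WT) and line 493 carried a Kmt2d mutation (mutant). KMT2D is a histone H3 lysine 4 methyltransferase that acts mainly at enhancers, and the question addressed here is where it sat in the WT line and how its partners, the SWI/SNF remodelling complexes and the TFAP2 and SOX10 factors were placed in the line with the mutant gene. Of 24 samples, 22 had a peak list (10 WT, 12 mutant), with 197727 peaks in all. The other 2 were rabbit IgG controls, 1 per line, whose signal was not analysed here. H3K4me3, SMARCC1, ARID1A, ARID2, PBRM1, BRD9, Menin, UTX and TFAP2A (9 targets) had a list in both lines. KMT2D was used here in the WT line only, and TFAP2B and SOX10 (antibodies T and U) in the mutant line only. Each line and target had 1 library, so no replicate check and no test was possible, and with 1 line per genotype the line and the genotype cannot be told apart. Intervals are 95% intervals for counting error only. Fold enrichment is the authors' value and is compared only within a list.

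The Kmt2d gene itself kept an H3K4me3 peak at a gene end in both lines, with a fold enrichment of 22.1 in the WT list and 34.0 in the mutant list. Over the 9 paired targets, the Kmt2d locus with 20 kb on each side held 12 WT and 18 mutant peaks, among them 5 H3K4me3 peaks in each line and 5 WT and 8 mutant Menin peaks. A TFAP2A peak lay at a Kmt2d gene end in the mutant line only. Peak lists carry no sequence and no protein level, so these values check neither the mutation nor its effect on the protein.

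KMT2D sites in the WT line were mainly distal and most were shared with UTX, the H3K27 demethylase that sits in the same complex, and with ARID1A, the subunit that defines canonical SWI/SNF (BAF). The highest fold enrichment of KMT2D lay at the gene end of Sp1, which encodes a general transcription factor. That site held peaks of 7 WT and 8 mutant libraries, so it was not particular to KMT2D. High gene-end sites also included Pip5k1c, Dazap1 and Gamt, the last encoding an enzyme of creatine synthesis. High distal sites lay near Hbegf, which encodes an EGF-family growth factor, near the clock gene Arntl and inside Ptprs, a receptor phosphatase gene. H3K4me3 covered the minority of KMT2D sites.

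In numbers, KMT2D gave 6434 peaks, 28.0% of them within 1 kb of a gene end (26.9–29.1%) and 57.9% more than 5 kb from any. UTX overlapped 88.3% of KMT2D peaks (87.5–89.1%) and ARID1A 87.7% (86.8–88.5%), against 0.389% and 0.792% in shuffled positions. With equal numbers of top peaks these became 76.5% and 48.1%. TFAP2A overlapped 57.7%, the SWI/SNF core subunit SMARCC1 48.0%, Menin, a subunit of the KMT2A and KMT2B complexes, 37.7%, and H3K4me3 34.7% (with equal numbers 42.0%, 34.5%, 22.5% and 19.1%). ARID2 (4.79%), PBRM1 (1.45%) and BRD9 (1.32%), which mark the PBAF and non-canonical BAF complexes, had lists too short (689, 343 and 141 peaks) to cover many KMT2D peaks. Read the other way, 60.3% of BRD9 peaks carried KMT2D, 57.8% of UTX, 44.7% of ARID2, 31.7% of TFAP2A, 27.1% of PBRM1, 26.8% of SMARCC1, 25.2% of ARID1A, 18.0% of Menin and 15.3% of H3K4me3 peaks. Location separated the partners. UTX and ARID1A lay on 83.4% and 76.9% of gene-end KMT2D peaks and on 90.9% and 93.5% of those beyond 5 kb. SMARCC1 went from 12.2% to 66.2%, and H3K4me3 went the other way, from 81.6% to 11.9%, as did Menin, from 72.1% to 21.1%. KMT2D peaks with both UTX and ARID1A numbered 5183 (80.6%), and 3594 (55.9%) had both and no H3K4me3. Only 292 (4.54%) had neither.

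The Sp1 site (chromosome 15, 102405317 to 102406887) had the top KMT2D fold enrichment, 210, followed by the shared end of Hdgfl2 and Ubxn6 (159), that of Cactin and Pip5k1c (140), that of Mylpf and Tbc1d10b (139), that of Dazap1 and Gamt (126), and Arrdc2 (123). The highest distal sites were inside Ptprs (118; 13998 bp from its nearer end), 42820 bp from Tex44 (115), 30414 bp from Arntl (111) and 11998 bp from Hbegf (109). All of these sites carried a UTX peak in both lines. Many were called in most lists: Sp1 in 7 WT and 8 mutant libraries, Cactin and Pip5k1c in 8 and 10, Mylpf and Dazap1 in 7 and 8. The site near Hbegf was called in 5 and 6. Such sites were not particular to KMT2D. The distal sites with Mc2r (99.6, 262837 bp away) and Cd209a (82.2, 5463 bp away) as nearest genes also had a BRD9 peak in both lines, which the site near Hbegf lacked. The mutant BRD9 list is of doubtful value (below), and 15.6% of WT BRD9 peaks lay in regions called in at least 15 libraries. Among the gene lists, KMT2D marked gene ends of Pmel and Erbb3 (pigment cell genes), Axl, Jun and Vim (mesenchymal state), Pgk1, Eno1 and Pkm (glycolysis), Igfbp6 and Pik3r1 (IGF signalling), and Kmt2a, Kmt2b, Setd1a, Setd1b and Men1 (COMPASS). It also marked Smarca4, Smarcd2, Actl6a, Arid1a, Bcl7b and Bcl7c (SWI/SNF), Trp53, Col1a1 and Rpl4. No Hoxa or Hoxb gene, keratinocyte, blood cell or endothelial marker had a KMT2D peak at a gene end; 2224 of 21900 protein-coding genes had one.

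**Figure D1:**
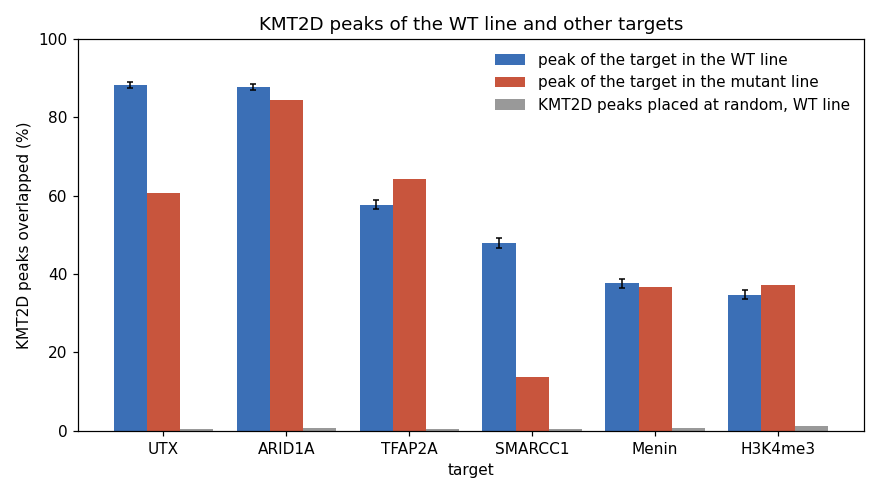
Share of the 6434 WT KMT2D peaks overlapped by each target in each line and after random placement, with 95% counting intervals on the WT bars.

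H3K4me3 at gene ends was largely the same in the WT and mutant lines, and the differences were mostly peaks present in the mutant line only. Mutant-only genes included Col6a3, which encodes a collagen VI chain, Crabp1, which encodes a retinoic acid binding protein, and the Wnt pathway genes Daam2 and Nkd2. Of the lists, pigment cell genes gained Sox10, the neural crest and melanocyte regulator, and Rab27a, which moves melanosomes. The fold enrichment at Sox10 (8.37) and Rab27a (7.72) was under the mutant list median of 16.5, though both stayed gains at a −log10 q of at least 5. Hoxa3, Hoxa5 and Hoxa6 had H3K4me3 in the mutant line only, though Hoxa3 alone did among peaks with a −log10 q of at least 5. WT-only genes included Mtap, an enzyme gene of methionine salvage next to Cdkn2a, and Acvrl1, a BMP receptor gene.

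The WT list had 14666 H3K4me3 peaks and the mutant list 16438, 1.12 times as many (1.08 times after thinning to equal depth). Of WT peaks, 91.7% overlapped a mutant peak (91.2–92.1%), 98.0% within 1 kb of a gene end and 82.1% elsewhere. Peaks lay within 1 kb of a gene end in 60.3% of cases in both lines. An H3K4me3 peak at a gene end was present in the WT line alone for 119 genes and in the mutant line alone for 1114. The mutant library was called at the greater depth (2.21 M against 1.19 M fragments, M for mega, reconstructed from the lists), which gives it more power to find weak peaks.

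By fold enrichment within the mutant list, the highest genes without a WT H3K4me3 peak within 5 kb were Col6a3 (37.0), Crabp1 (24.3), Daam2 (24.1), Greb1 (23.0) and Klhl1 (22.8). Next came Asxl3, Nkd2, Hecw2, Plpp7 and Zcchc3, down to 20.5, of 850 such genes. Col6a3 (chromosome 1, 90766860 to 90844001) also had mutant ARID1A, Menin and TFAP2A peaks nearby, and Crabp1 and Klhl1 had ARID1A and Menin. Within the WT list the order was Mtap (33.2), Acvrl1 (13.2), C77080 (11.3), Akr1c18 and Cavin4 (10.9 each), then Mgst1, Ppp1r3d, Fgd3, Por and Pdpn, down to 8.07, of 76 genes. Near Mtap, Acvrl1, Mgst1, Por and Pdpn no paired target had a mutant peak within 5 kb.

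By list, genes with an H3K4me3 peak in the WT and mutant lines numbered 8 and 10 of 22 pigment cell genes, 17 and 18 of 20 mesenchymal state genes (gain of Ngfr, a neural crest receptor gene) and 17 and 18 of 20 glycolysis genes (gain of the lactate exporter gene Slc16a3). They numbered 12 and 14 of 22 IGF signalling genes, with gains of Igfbp4 and Igf2bp3. Counts were equal in the 2 lines for COMPASS (15 of 17), SWI/SNF (22 of 24), ribosomal protein (21 of 21) and tumour model genes (6 of 9). They were also equal for fibroblast (4 of 10), keratinocyte (2 of 8), blood cell (0 of 8) and endothelial markers (1 of 6). Hoxa and Hoxb genes went from 0 to 3 of 21, with 1 gain at a −log10 q of at least 5 and 6 gains when gene ends were taken as 2.5 kb. Of 12 silent tissue-restricted genes taken as a negative control, Apoa2 had a peak in both lines. No gene on any list lost its H3K4me3 peak. The pigment list gained more genes than 79.1% of random lists matched on fold enrichment and the mesenchymal list more than 13.7%. All 3 Hox genes with a mutant peak were gains, the most this comparison allows, against a random mean of 1.80. These peaks were weak: the fold enrichment was 6.07 at Hoxa3 and 4.1 at Hoxa5 and Hoxa6, against a list median of 16.5. Hoxa5 and Hoxa6 are neighbours with the same value, so 1 peak may have been counted for both.

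Around Sox10 with 20 kb on each side, the paired targets held 2 WT and 13 mutant peaks (6 mutant H3K4me3, 5 TFAP2A and 2 ARID1A peaks), and SOX10 antibody U added 3. The WT line had no peak of any target from 79142399 to 79229137 on chromosome 15, where the mutant line had 36. The Hoxa cluster held 0 WT and 8 mutant peaks (4 H3K4me3 and 4 TFAP2A) and the Hoxb cluster 0 and 4. Of the pigment enzyme genes, Tyr had 0 and 2 peaks, Tyrp1 0 and 3, and Dct 1 and 1. Mitf had 11 and 15. Nrg1, which encodes a ligand of ERBB receptors, ran the other way, with 30 WT and 11 mutant peaks. Much of this came from ARID1A (12 and 6) and SMARCC1 (8 and 0), while TFAP2A had 4 and 3 and H3K4me3 2 and 1. The mutant SMARCC1 library was called at lower depth and had far fewer peaks everywhere (below), so the pooled count overstates the contrast at Nrg1. These loci were picked after the gene values had been seen.

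Around Cdkn2a each line had a long stretch without peaks. The mutant line had none from 88951385 to 89351015 on chromosome 4 (400 kb), where 8 WT libraries had 63 peaks, 8 of them H3K4me3. The WT line had none from 89146570 to 89514900 (368 kb), where 10 mutant libraries had 41 peaks. Their overlap, 204 kb with Cdkn2a and Cdkn2b, held 0 peaks over all 22 libraries. Mtap spans the edge: its WT-only peak lies just outside the shared empty stretch.

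**Figure D2:**
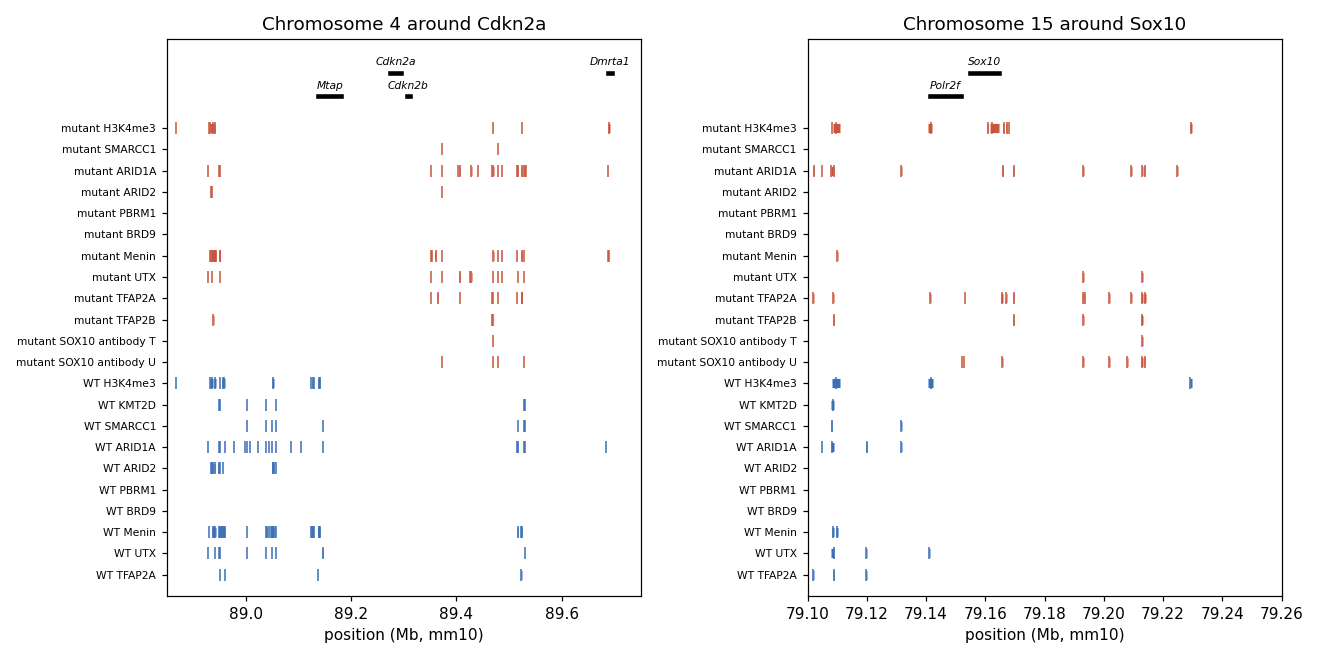
Peaks of every library across the Cdkn2a region and the Sox10 region. Ticks mark summits, bars mark peak spans and colours mark the lines.

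TFAP2A, a neural crest transcription factor, had peaks as called at many more gene ends in the mutant line than in the WT line, at unequal depth. Within the mutant list the highest mutant-only gene ends were those of Eif1ax, a translation initiation gene, Cbwd1, the fatty acid transporter gene Slc27a6 and Ltc4s, a leukotriene synthesis gene. Of the mesenchymal state genes, Ngfr, Axl, Sox9, Sox2, Snai2, Twist1 and Tgfbi carried TFAP2A in the mutant line only. Of these, Axl and Sox9 dropped out and Zeb1 and Tead1 came in when gene ends were taken as 2.5 kb, and Tgfbi dropped out and Jun and Foxd3 came in at a −log10 q of at least 5. WT-only gene ends included Cnksr1 and the epidermal genes Sprr2a1 and Sprr2a3.

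TFAP2A peaks numbered 11636 in the WT line and 18530 in the mutant line, 1.59 times as many and 1.19 times after thinning to equal depth. Of WT peaks 82.5% overlapped a mutant peak (81.8–83.2%), and of mutant peaks 52.6% overlapped a WT peak. Gene-end WT peaks were kept in 93.8% of cases, all others in 75.0%. A TFAP2A peak at a gene end was present in the WT line alone for 265 genes and in the mutant line alone for 2328. These 2 counts were not thinned. The mutant library was called at the greater depth (2.16 M against 1.19 M fragments), which gives it more power to find weak peaks. Within the mutant list the median fold enrichment was 5.94 at mutant-only peaks and 13.2 at shared ones. Fold enrichment within the mutant list was 76.4 at Eif1ax, 42.5 at Cbwd1, 36.4 at Slc27a6, 34.8 at Ltc4s and 33.1 at Hr, then fell through Slc4a7, Peli1, Vps26a and Ttll13 to 27.1 at Dhcr7. Within the WT list it was 12.6 at Cnksr1, Sync and Btbd2, 10.9 at Mfsd12 and Sprr2a1, 10.4 at Mapkapk3 and Rpl32, and lower at Sprr2a3, Ctsz and Arhgef17.

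Mesenchymal state genes with TFAP2A at a gene end numbered 5 in the WT line and 12 in the mutant line. This gain was larger than in 89.1% of matched random lists. Ribosomal protein genes went from 4 to 13 (larger than in 88.7%), so the gain was not particular to the mesenchymal list. COMPASS genes went from 9 to 12 (Kmt2d, Setd1b and Wdr5), SWI/SNF genes from 11 to 16, and IGF signalling genes from 6 to 10, gains near the means of matched random lists (3.73, 4.91 and 3.36). Among fibroblast markers Pdgfrb and Thy1 lost TFAP2A, and 3 genes in the WT line became 1, a loss larger than in 97.8% of matched random lists. The keratinocyte marker Krt10 and the blood cell marker Cd68, each the 1 gene of its list with TFAP2A in the WT line, also lost it. Hoxb9 gained it.

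UTX peaks as called were as many in the mutant line as in the WT line, though fewer after thinning to equal depth. Only about as many were shared as were not. KMT2D was more common at shared UTX sites than at WT-only ones, and SOX10 of the mutant line lay at many UTX sites of the mutant line, shared or not, and at few WT-only ones. Gene ends with UTX in the WT line alone included Ccdc114, Atp8b3, Pbx4 and the replication-dependent histone genes H4c14, H2bc9 and H3c7. Those in the mutant line alone included Lama4, a laminin gene, Lpp, and Eed, which encodes a Polycomb subunit. Of the glycolysis genes, Hk2, Pfkl, Gapdh and Eno1 had UTX in the WT line only; at a −log10 q of at least 5 these were Gapdh, Pgk1 and Eno1.

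UTX gave 9712 WT and 9707 mutant peaks, a ratio of 0.999 (0.844 after thinning to equal depth), and covered 0.730 times as much sequence in the mutant line. Of WT UTX peaks 53.3% overlapped a mutant peak (52.3–54.3%). KMT2D lay on 71.6% of shared WT UTX peaks and on 41.9% of WT-only ones. SOX10 (antibody U, mutant line) lay on 39.2% of the 4408 mutant-only peaks, 39.9% of shared mutant peaks and 5.36% of the 4534 WT-only positions, and mutant ARID1A on 76.2%, 95.3% and 62.9%. A UTX peak at a gene end was found in the WT line alone for 970 genes and in the mutant line alone for 468. Fold enrichment within the WT list was 60.8 at Ccdc114, 37.5 at Atp8b3, 31.2 at Pbx4, 28.9 at Gpbp1, 28.0 at H4c14 and 26.5 at Cct7 and Pradc1, followed by Dop1b, H2bc9 and H3c7 (25.9 each). Within the mutant list it was 20.5 at Lama4, followed by Lpp, then 17.5 at Dmxl1, 15.7 at Agfg2, Eed and Erp27, and 14.8 at Chl1, with Dgat2, Phrf1 and Psip1 at 13.9. Glycolysis genes with UTX went from 6 to 4, with gains at Slc2a1 and Pdk1. The loss of 4 genes was larger than in 80.7% of matched random lists. COMPASS genes went from 7 to 4 (losses at Setd1a, Paxip1 and Hcfc1) and IGF signalling genes from 4 to 2 (Irs2 and Akt2), losses near the means of matched random lists (3.05 and 1.58).

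Menin followed H3K4me3 in both lines and covered the gene ends of nearly all SWI/SNF genes. Mutant-only gene ends included Lcmt1, Eif3l, Ksr1, a RAS pathway scaffold gene, and Shox2. WT-only ones included Pcdh1, Lgmn, a lysosomal protease gene, and the adhesion genes Icam4 and Icam5. Mitf, the melanocyte master regulator, had Menin at a gene end in the mutant line only. Its fold enrichment of 4.82 was under the list median of 6.54. Mitf was the 1 pigment cell gene gained, against a random mean of 0.624, and 1813 of all genes were mutant only.

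Menin peaks numbered 13481 and 16773, 1.24 times as many in the mutant line, but 0.844 times as many after thinning to equal depth. The direction thus depended on the thinning, which changed depth and the −log10 p cutoff together (lowest value 3.69 in the mutant list, 3.91 in the WT list). Of WT peaks 77.0% overlapped a mutant peak (76.3–77.7%), 88.8% at gene ends and 67.4% elsewhere. H3K4me3 lay on 78.9% of WT and 82.5% of mutant Menin peaks. Fold enrichment in the mutant list was 17.4 at Lcmt1, 16.8 at Eif3l and Ksr1, 16.3 at Shox2, 15.1 at Smc5, 14.9 at Dmrta1, 14.5 at Pxmp4 and 14.0 at H2ac23 and H2bc23. In the WT list it was 15.4 at Pcdh1, 12.9 at Lgmn and 11.3 at Cavin4 and Tmeff1, then fell through Nudt13, Fem1a, Crim1 and Mrps14 to 9.75 at Icam4 and Icam5. Genes with Menin went from 21 to 22 for SWI/SNF, from 12 to 14 for COMPASS and from 13 to 17 for ribosomal protein genes. A peak at a gene end was in the WT line alone for 420 genes and in the mutant line alone for 1813.

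The SWI/SNF subunits behaved differently from each other between the lines. SMARCC1 had far fewer peaks in the mutant line, with WT-only gene ends such as Naa11, Jrk, Opn3 and Gstm7, while ARID1A kept its number. ARID1A was lost with SMARCC1 at Jrk, Naa11 and Pate1, and gained at Myl6b, Mbd3, Asah1 and at Smarca2, which encodes a SWI/SNF ATPase. PBRM1 peaks, few in both lines, sat at active gene ends such as those of the ribosomal protein gene Rps18, of Trp53 and of Actl6a and Brd9. BRD9 peaks lay mostly away from gene ends.

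SMARCC1 gave 11507 WT and 2910 mutant peaks, a ratio of 0.253. The mutant library was called at 0.405 M fragments against 1.03 M, and thinning to equal depth gave 0.381; with peaks at a −log10 q of at least 5 the ratio was 0.138. Of WT SMARCC1 peaks 16.9% overlapped a mutant one (16.2–17.6%), while 67.3% of mutant peaks overlapped a WT one. This asymmetry followed the lengths of the lists: with equal numbers of top peaks 38.7% of WT peaks were shared, and of SMARCC1 mutant peaks shared with the WT line there were 39.1%. WT SMARCC1 peaks lay on ARID1A in 87.9% of cases (87.3–88.5%) and mutant ones in 86.1% (84.8–87.3%; 44.8% with equal numbers of top peaks). ARID1A peaks lay on SMARCC1 in 45.4% of cases in the WT line and 9.80% in the mutant line. At the 9565 WT-only SMARCC1 sites ARID1A went from 85.9% in the WT line to 70.5% in the mutant line, and at shared sites from 97.6% to 98.9%, and the WT fold enrichment was lower at the WT-only sites (median 7.16 against 13.4). SMARCC1 was rare at gene ends in both lines (4.28% and 3.75% of peaks), and no gene list had it at more than 2 genes. Fold enrichment in the WT list was 24.2 at Naa11, 23.3 at Jrk and Opn3, and 18.8 at Gstm7, then fell through Dtd2, Zc3h14, Akr1c18, Fam50b and Mast2 to 16.0 at Pate1. In the mutant list it was 8.69 at Slc13a3 and 5.74 at Pcx, then fell through Casc1, Lrmp, Nppb, Ufl1, Clec2h and Pola2 to 4.72 at the shared end of the antigen-processing genes Psmb9 and Tap1.

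ARID1A gave 22199 WT and 25385 mutant peaks, a ratio of 1.14, and 70.9% of WT peaks were shared (70.3–71.5%). Fold enrichment in the WT list was 27.0 at Jrk, 22.4 at Naa11 and 21.1 at Atf6, an unfolded protein response gene, then fell through Trpm3, Pate1, Fabp3, Ugt1a6b, Rnf14 and Cx3cr1 to 12.8 at Dcaf15. In the mutant list it was 28.2 at Myl6b, 23.6 at Ormdl2 and Sarnp, 23.5 at Asah1, 22.8 at Mbd3 and Pqlc3, 20.7 at Cdc25c and Smarca2 and 20.5 at Glyr1 and Rogdi. SWI/SNF genes with ARID1A went from 5 to 10 (Smarca2, Smarcb1, Arid1a, Bicra and Bicral), glycolysis genes from 6 to 10, and IGF signalling genes from 3 to 7 (Insr, Irs1, Irs2 and Akt2). Matched random lists gained 3.91, 4.64 and 2.56 genes on average, and over all genes ARID1A was at a gene end in the WT line alone for 605 and in the mutant line alone for 1739.

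Of the smaller lists, ARID2 had 689 WT and 456 mutant peaks (ratio 0.662, and 0.369 at equal depth), PBRM1 343 and 431 (1.26, and 0.863 at equal depth), and BRD9 141 and 90 (0.638, and 0.511 at equal depth). The direction for PBRM1 thus depended on the thinning. PBRM1 peaks lay at gene ends in 85.4% of WT cases (81.3–88.8%) and 74.9% of mutant cases (70.6–78.8%), and on H3K4me3 in 92.1% and 87.9%. ARID2, its PBAF partner, lay on ARID1A in 58.3% and 56.6% of cases and on PBRM1 in 3.05% and 12.3%, and PBRM1 lay on ARID2 in 6.12% and 13.0%, low shares that the short lists limit in part. BRD9 peaks lay on UTX in 69.5% and 63.3% of cases. The mutant BRD9 list was of doubtful value as a map of binding: its median fold enrichment was 2.17, 25 of its 90 peaks lay on unplaced sequence, and 56.7% lay on ARID2 and 47.8% on PBRM1. Of WT peaks, 70.6% were shared for PBRM1 (65.5–75.1%), 35.6% for ARID2 (32.1–39.2%) and 30.5% for BRD9 (23.5–38.5%). The fold enrichment of PBRM1 at Rps18 was 37.3 in the WT list and 39.4 in the mutant list; these PBRM1 genes were chosen after their values were seen.

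**Figure D3:**
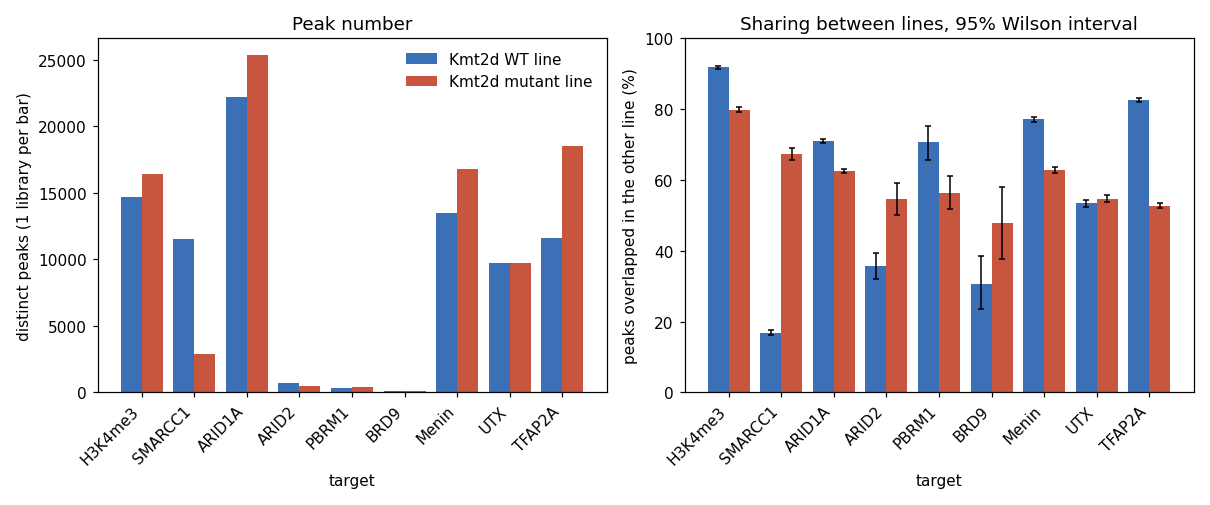
Number of peaks per target in the WT and mutant lines, and the share of each list overlapped by a peak of the other line, with 95% counting intervals.

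Sites that held KMT2D in the WT line did not lose UTX, ARID1A, SMARCC1 or TFAP2A more often than other sites in the mutant line. Peaks of these targets at KMT2D sites were kept more often than peaks of like strength elsewhere. Sp1, Hdgfl2, Arntl and Hbegf, among the highest KMT2D sites, kept UTX and TFAP2A. These sites also held peaks of many other targets in both lines. Menin was kept less often at KMT2D sites and H3K4me3 hardly differed, but the direction for Menin turned when peaks were also matched on UTX.

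Matched on fold enrichment and distance to a gene end, UTX peaks with KMT2D were kept in 64.1% of cases against 55.4% without, a difference of 8.69 percentage points (4.40–13.0). This covers 5272 of the 5609 UTX peaks with KMT2D, those in classes that also held peaks without it. Over all 5609, 66.1% were kept. ARID1A peaks were kept in 89.3% against 81.0% (8.21; 7.09–9.32), SMARCC1 in 26.6% against 20.6% (6.03; 4.25–7.81) and TFAP2A in 89.5% against 86.1% (3.42; 2.30–4.54). H3K4me3 peaks were kept in 92.6% against 93.3% (−0.680; −1.56 to 0.197) and Menin peaks in 78.4% against 81.4% (−3.05; −4.56 to −1.54). For Menin the difference was 1.23 points at gene ends (−0.241 to 2.69) and −7.68 farther than 1 kb from them. For SMARCC1 it was 1.67 at gene ends (−3.36 to 6.70), where no difference was detectable, and 6.37 elsewhere. For ARID1A it was 12.5 and 6.80, for TFAP2A 1.83 and 4.35, and for UTX it was positive in both parts (6.89 away from gene ends). Matching on peak width in place of fold enrichment raised the UTX difference to 25.4 points, and no matching to 30.4. Among peaks with a −log10 q of at least 5 it fell to 5.74. Its size thus rests on the matching and the cutoff while its sign does not. Without matching the Menin difference was 1.69. Matched also on a WT UTX peak, which lies on most KMT2D sites, the differences were 5.42 for ARID1A, 3.71 for SMARCC1, 4.35 for TFAP2A, 1.5 for H3K4me3 and 4.0 for Menin. Over the other settings the difference ran from 2.78 to 13.3 for SMARCC1, reached 24.6 for ARID1A and 10.3 for TFAP2A, and ranged down to −5.65 for Menin. Over all KMT2D sites, UTX overlap still fell, from 88.3% in the WT line to 60.6% in the mutant line, and SMARCC1 overlap fell from 48.0% to 13.8%, while in the mutant line ARID1A overlapped 84.3%, TFAP2A 64.3%, Menin 36.6% and H3K4me3 37.2%.

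**Figure D4:**
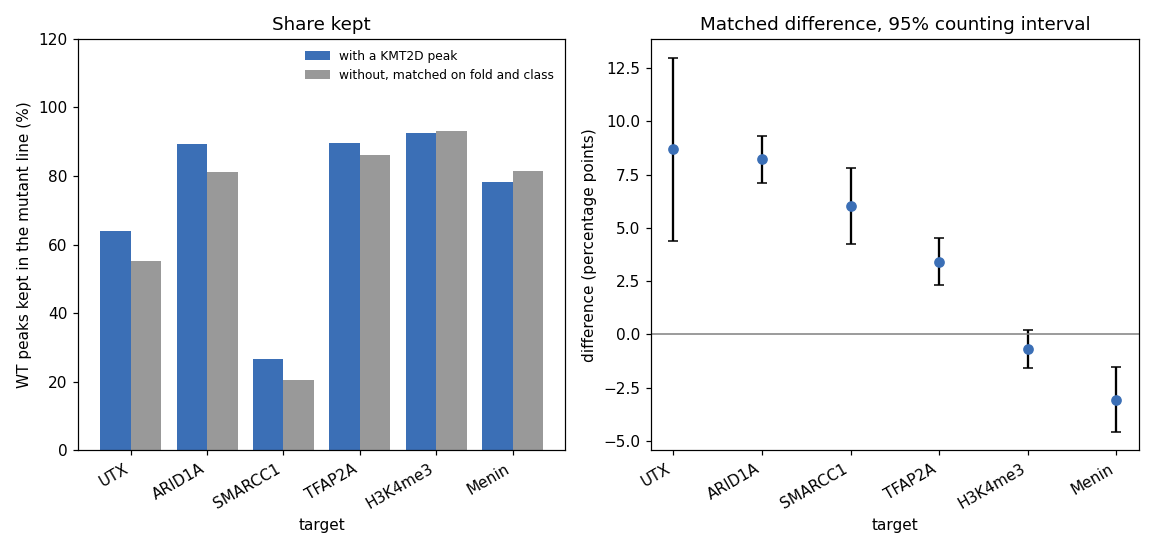
Share of WT peaks kept in the mutant line with and without a KMT2D peak, matched on fold enrichment and gene-end class, and the difference with 95% counting intervals.

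In the mutant line TFAP2B sat almost wholly within TFAP2A sites, and SOX10 lay mainly at distal sites with ARID1A and UTX. TFAP2B marked gene ends of 8 of 20 mesenchymal state genes (Ngfr, Sox9, Sox2, Twist1, Nes, Cdh2, Foxd3 and Vim), and of the pigment genes only Pmel. Over all genes the share was 21.9%. TFAP2B also marked 8 of 20 glycolysis, 8 of 22 IGF signalling, 10 of 24 SWI/SNF and 5 of 21 ribosomal protein genes. The mesenchymal share was thus not particular to that list. SOX10 antibody U marked gene ends of Sox2, Vim, Pgk1, Pdk1, Pik3r1, Men1, Hcfc1, Smarca2, Actl6a, Arid1a, Arid2 and Postn. It marked none of the 22 pigment cell genes, where 3.83% of all genes were marked. With 20 kb on each side it had peaks at Mitf and Sox10 (3 each), Erbb3 (2), and Pax3, Mc1r, Tyr and Tyrp1 (1 each). SOX10 antibody T marked none of the list genes.

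TFAP2B gave 8678 peaks, 94.0% of them on TFAP2A (93.5–94.5%), while 43.1% of TFAP2A peaks carried TFAP2B. TFAP2B lay at gene ends in 48.7% of cases and on H3K4me3 in 64.2%. It marked 11 of 17 COMPASS genes. SOX10 antibody T gave 1163 peaks and antibody U 6358. Of T peaks 83.7% lay on U peaks (81.4–85.7%; 47.3% with equal numbers of top peaks), and of U peaks 15.3% lay on T peaks. U peaks were beyond 5 kb from a gene end in 79.1% of cases and lay on ARID1A in 74.7% (73.6–75.8%; 34.8% with equal numbers), UTX in 60.7%, TFAP2A in 48.4% and SMARCC1 in 12.6%. T peaks lay on ARID1A in 88.4%, UTX in 84.6% and TFAP2A in 66.0%. Of the WT KMT2D sites 45.1% carried TFAP2B and 27.3% carried SOX10 U in the mutant line.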

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

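The equal-depth thinning, the matching on UTX and the removal of regions called in at least 15 libraries were chosen after the results were seen, and the other alternatives before. No paired analysis was possible because each line and target had 1 library and all libraries had replicate number 1, so no test was run in either form. A motif alternative was not run, since no genome sequence was used here. A share or retention difference counted as the same inside the 95% interval of the main result, and as moved outside it. Ratios have no interval and had a wider margin. The UTX number ratio counted as the same at 0.844 against 0.999, the SMARCC1 ratio as moved at 0.381 against 0.253. A value reversed when its direction changed, unless the main interval left the direction open. Of 178 values for 37 main results, 97 stayed the same, 77 moved and 4 reversed. Of 951 values for 281 others, 614, 333 and 4 did. Depth limits the number of weak peaks, so a peak missing from 1 list was not detectable at that depth and need not be absent. Except where the construction shows it, the cause was not tested.

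With depth made equal, the number ratio was 0.381 for SMARCC1 and 0.369 for ARID2. It reversed for Menin (0.844) and PBRM1 (0.863), as did covered sequence for ARID1A (0.99) and PBRM1 (0.933). Thinning scaled called peaks and took the −log10 p cutoff of the other list, without calling peaks anew. These directions thus depended on the thinning, and depth alone was not shown to set them. The shared share of WT peaks was 68.6% for ARID1A, 90.8% for H3K4me3, 65.8% for Menin, 22.6% for SMARCC1, 75.0% for TFAP2A and 48.6% for UTX. The TFAP2A retention difference was 4.90 points.

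With equal numbers of top peaks by fold, sharing was 66.4% for ARID1A, 89.1% for H3K4me3, 70.5% for Menin, 38.7% for SMARCC1 and 69.2% for TFAP2A. KMT2D peaks were overlapped by ARID1A in 48.1%, H3K4me3 in 19.1%, Menin in 22.5%, SMARCC1 in 34.5%, TFAP2A in 42.0% and UTX in 76.5%. Smaller lists lower overlap by construction. Retention differences were 8.76 points for SMARCC1 and 5.37 for TFAP2A. SMARCC1 lay on ARID1A in 67.8% (WT) and 44.8% (mutant), SOX10 T on U in 47.3%, SOX10 U on ARID1A in 34.8% and TFAP2B on TFAP2A in 76.3%.

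Matching retention on peak width gave differences of 11.2 points for ARID1A, −0.957 for Menin, 9.19 for SMARCC1, 5.53 for TFAP2A and 25.4 for UTX; the cause was not tested. Without matching they were 24.6 for ARID1A, 1.11 for H3K4me3, whose main interval held 0, 1.69 (reversed) for Menin, 13.3 for SMARCC1, 10.3 for TFAP2A and 30.4 for UTX; which part of the matching caused this was not tested. Matching also on a WT UTX peak gave 5.42 for ARID1A, 1.5 for H3K4me3, 3.71 for SMARCC1 and 4.0 for Menin (reversed); the cause was not tested. Counting peaks within 1 kb as kept gave −5.65 for Menin; the cause was not tested.

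With −log10 q of at least 5, sharing was 68.5% for ARID1A, 96.6% for H3K4me3, 71.8% for Menin, 11.5% for SMARCC1, 79.6% for TFAP2A and 46.9% for UTX. The SMARCC1 number ratio was 0.138, and covered sequence was 0.975 for ARID1A and 1.00 for BRD9, both reversed. Retention was 0.746 for H3K4me3 and 2.78 for SMARCC1. KMT2D was overlapped by ARID1A in 85.7%, H3K4me3 in 30.7%, Menin in 31.3%, SMARCC1 in 44.2%, TFAP2A in 56.2% and UTX in 90.8%. SMARCC1 lay on ARID1A in 91.1% (WT) and 98.6% (mutant), SOX10 U on ARID1A in 69.8% and TFAP2B on TFAP2A in 95.5%. H3K4me3 at Hox genes was gained by 1 gene, Hoxa3. The cause was not tested.

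With at least 50% of the shorter peak overlapped, sharing was 69.8% for ARID1A, 90.4% for H3K4me3, 73.3% for Menin and 80.9% for TFAP2A. KMT2D was overlapped by ARID1A in 86.7%, H3K4me3 in 26.7%, Menin in 35.0%, SMARCC1 in 46.7% and TFAP2A in 55.4%. SMARCC1 lay on ARID1A in 86.4% (WT) and 84.4% (mutant), SOX10 U on ARID1A in 73.5% and TFAP2B on TFAP2A in 92.6%. A stricter overlap can only lower these.

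With gene ends taken as 2.5 kb, 6 Hox genes gained H3K4me3 and 35.3% of KMT2D peaks lay at gene ends, which a wider window raises by construction. Without regions called in at least 15 libraries, H3K4me3 overlapped 33.5% of KMT2D peaks; the cause was not tested. With autosomes only, run for peak number and covered sequence alone, all 18 values counted as the same by the rule above. Within that margin the BRD9 ratio fell from 0.638 to 0.478 in number and from 0.779 to 0.595 in covered sequence.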

Other observations

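All tests of the SMARCC1 pattern were chosen after the results were seen, as was the UTX test of recurrent regions; the UTX tests of 50 fold classes, shared ARID1A sites and sites open to many targets were written before their values, the last of these once the other UTX values were known.

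Fewer SMARCC1 peaks in the mutant line, 0.253 times as many, may have a technical or a biological source. Lower depth as the whole cause would give equal numbers once the WT library was thinned to the mutant depth, yet the ratio was 0.381 (0.365–0.397), so depth alone is unlikely as far as the reconstructed depths hold. Loss of ARID1A-containing complexes at the WT-only sites would lower ARID1A there, but ARID1A peaks were kept 2.62 points more often (1.08–4.17) than those of like strength without SMARCC1. ARID1A still fell from 85.9% to 70.5% of the WT-only sites, so its loss at a part of them stays open. Weaker enrichment in the mutant SMARCC1 library as a whole would make the share kept rise with WT fold enrichment. It rose 11.3-fold from the lowest to the highest class. Stronger peaks are kept more often in any pair of libraries, and many kinds of partial loss would give the same. The rise therefore cannot decide for or against weaker enrichment. A repeat SMARCC1 library of the mutant line at matched depth, beside a blot of SMARCC1, could separate these.

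UTX peaks with KMT2D were kept more often than UTX peaks without. With 50 fold classes in place of 10 the difference was 11.6 points (8.60–14.6). Each matched value leaves out peaks with KMT2D in classes that held no peak without it, so remaining peak strength cannot be excluded. Shared ARID1A sites (9.62, interval 5.61–13.6) and sites open to many targets (8.17, interval 4.17–12.2) are unlikely as the whole source. The difference also stayed without recurrent regions (12.3, interval 4.41–20.3). These held only 157 WT UTX peaks (1.62%) and were defined partly from the UTX and KMT2D lists. The sites may hold UTX through factors that KMT2D does not place, such as TFAP2A or a remaining KMT2C complex, or the mutant protein could still be present. UTX mapped after acute removal of KMT2D within the WT line would show whether UTX there depends on KMT2D, but would not separate these explanations.

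The source of the stretches without peaks around Cdkn2a was not tested, since they were found by their contrast between the lines and no reads were used here to measure DNA content. Copy number from sequencing of both lines would be the test.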
